A study of Mus musculus with 2 samples.

How the data were processed

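H3K27me3 was profiled by chromatin immunoprecipitation and sequencing of forebrain tissue from mouse embryos at day 12.5. The 2 samples are biological replicates per the labels, each a pool of embryos of both sexes, and form 1 group, so that no groups were compared. The antibody target, the tissue and the genome build mm10 come from the labels. Per the README files deposited with the samples, alignments and control alignments were the inputs of the peak calls, the pooled list was called on both replicates together, and the replicated list was derived from the pooled list and the lists of each replicate. The aligner, the peak caller, their versions and thresholds are not given in the sources used here.

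All 4 peak lists are in the narrowPeak format, per the file headers and README texts. The signal value of a peak is its enrichment as the authors' caller gave it, with a normalization that is not given in the sources used here. The −log10 p and −log10 q of each peak are the authors' own, with a lowest −log10 p of 2.00 in the replicate 1 list. The score of a peak is a display value that the authors scaled within each list, and it was not used. Peak values are the authors' own. They served to describe, rank or filter peaks within a list, to compare signal between promoters within the replicated list, and for a rank correlation of −log10 p between the replicate lists. Heights were not compared between lists in any other way. The lists hold no counts or depths, so the depth of each sample is unknown. The longer list of replicate 2 cannot be assigned to depth or to the tissue, and a promoter without a peak is one where none was called, which is not evidence that the mark was absent. A caller of narrow peaks can split wide H3K27me3 domains into many peaks, which is why peak numbers are given beside covered bases.

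Gene models were taken from GENCODE release vM21 and sequence from GRCm38.p6, which share chromosome names and lengths with mm10; no peak ended beyond a chromosome. The analysis used chromosomes 1 to 19, X and Y, with 21938 protein-coding genes. A single peak of replicate 1 on an unplaced contig was left out. The 5′ end of a gene was the outer end of its annotated span. Its promoter window reached 1 kb to each side and counted as marked when the list covered at least 200 bp of it. The covered share of the 10 kb window around the 5′ end gave the width of the mark. A promoter was CpG-rich when a 500 bp window within it, moved in steps of 50 bp, had at least 55% GC and a CpG observed to expected ratio of at least 0.75. Domains were replicated peaks joined across gaps of up to 3 kb and ranked by covered bases. Coordinates are given on mm10, counted from 1.

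The 17 gene lists, the main tests, the alternatives and the rule for naming genes were fixed before the data were examined. Exceptions are the settings, tests and named genes that are said below to be chosen after values or results were seen. All list symbols matched the annotation. Marked members of each list were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 17 lists, and pairs of lists by the same test with adjustment over 11 contrasts and conditional 95% intervals of the odds ratio. The threshold was an adjusted p of 0.05. A list's members are not independent replicates, so these tests describe the peak lists of these samples. Overlap of the replicates was tested by 1000 circular shifts of the replicate 2 peaks along each chromosome, one-sided, and the place of peak bases by 1000 shifts of the replicated peaks, two-sided. Priority ran from promoter windows to exons, introns and intergenic sequence.

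Genes were named by the following rule. From each list, the 3 marked members with the largest covered share and the first 3 unmarked members in list order were named. Up to 8 marked members were named for both forebrain lists and for housekeeping, pan-neuronal and Polycomb genes. The rule further took the 10 leading domains with up to 4 genes each, up to 5 members marked in 1 replicate alone per direction, and Gata2, Cdkn2a and Cdkn2b in any case.

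The procedures were tested on simulated data. Shifted peaks marked 5.88% of 21938 promoters by chance. Of 1000 random lists of 40 genes, 3.7% had p under 0.05 in the list test, and 0 after adjustment. With 10% or 30% of the 40 members drawn from marked genes instead of all genes, 21.2% and 87.6% of 1000 lists had p under 0.05. With 50% of 20000 peaks planted as shared, the overlap procedure returned 50.1%, and 2 of 40 unrelated lists had p under 0.05. In the test of promoter windows 1 of 40 shifted lists did.

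The alternatives were the list of each replicate alone, the pooled list, bases covered in both replicates, a minimum −log10 q of 2, other overlaps (1 bp or 1000 bp), a window of 5 kb to each side, any annotated transcript start, CpG-rich promoters alone, 1 gene per list within 100 kb, a looser CpG definition (50% GC, ratio of 0.6), joining gaps of 1 kb and 10 kb, an overlap of 50% of a peak and equal numbers of top-ranked peaks. Chosen after seeing the data were replicated peaks that overlap both replicates' peaks, a minimum −log10 q of 5, a background without chromosome Y, and the ratios of chromosome X in the other lists. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.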

Results

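H3K27me3, the trimethylated form of lysine 27 of histone H3 that Polycomb repressive complex 2 deposits at repressed genes, was mapped by chromatin immunoprecipitation and sequencing in mouse forebrain at embryonic day 12.5. The 2 samples were biological replicates of 1 group. Each came from its own pool of embryos of strain B6NCrl and of both sexes, with forebrains of 120 embryos in replicate 1 and of 68 embryos in replicate 2. The replicate 1 list held 122356 peaks over 54.9 Mb, or 2.08% of the sequenced genome, and the replicate 2 list held 193825 peaks over 85.6 Mb, or 3.23%. A list called on both replicates together (the pooled list) held 166662 peaks over 85.9 Mb. The list of replicated peaks, from which the values below come unless another list is named, held 82082 peaks over 64.3 Mb, or 2.43% of the genome, with a median width of 465 bp. The lists carry no read counts, so the depth behind a peak is unknown and no interval could be given for a peak's height. The design holds no contrast between conditions. The questions it can address are how far the replicates share their peaks and which genes and regions of the embryonic forebrain carry the mark.

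Both replicates placed H3K27me3 on the same core of developmental regulators. All 39 Hox genes, which pattern the body behind the forebrain, had a marked promoter in each replicate's list. So did all 48 transcription factors listed here for midbrain, hindbrain and spinal cord. Of all protein-coding genes, 4298 had a marked promoter in both lists, 342 in replicate 1 alone and 1695 in replicate 2 alone. Peaks of replicate 1 were shared with replicate 2 in 63.7% of cases, against 6.25% after circular shifts along each chromosome. Peaks of replicate 2 were shared with replicate 1 in 36.5% of cases, against 3.96% after shifts. The bases covered in both lists came to 37.7 Mb, a Jaccard index of 36.6% against 1.44% after shifts. Each of these comparisons gave p = 0.001 (one-sided permutation test with 1000 shifts), the smallest value the shifts can give. The 1000 top-ranked peaks of either replicate by the authors' p were all shared. Shared peaks were wider than the others, with medians of 330 bp against 219 bp in replicate 1 and 417 bp against 241 bp in replicate 2. An overlap of 1 bp counted as shared, which a wider peak meets more easily, so the way of counting can give part of this difference. Across the 62159 replicated peaks that overlapped a peak of both replicates, the authors' −log10 p in the replicate lists correlated with Spearman's rho of 0.540, over peaks that are not independent replicates. The replicated list itself was a subset of the pooled list. In it, 75.7% of peaks overlapped both replicates' peaks by at least 1 bp, 18.8% overlapped replicate 2 alone, 4.89% overlapped replicate 1 alone and 0.614% overlapped neither.

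Promoters were the sequence where H3K27me3 peaks were most concentrated. Promoter windows, reaching 1 kb to each side of a gene's annotated 5′ end, held 9.13% of peak bases against 1.71% of shifted peaks, a 5.36-fold excess. Exons outside these windows held 8.66% against 4.65%, a 1.86-fold excess, and intergenic sequence held 38.8% against 51.4%, a ratio of 0.755. All 3 differences gave p = 0.001 (two-sided permutation test), the smallest value the shifts can give. Introns held 43.4% of peak bases against 42.2% of shifted peaks and did not pass the test (permutation p = 0.285). A promoter was counted as marked where peaks covered at least 200 bp of its window. By this measure 4905 of 21938 protein-coding genes were marked, or 22.4%, with 21.2% in the replicate 1 list and 27.3% in the replicate 2 list. CpG-rich promoters were marked more often than the others, in 2728 of 10422 cases (26.2%) against 2177 of 11516 (18.9%), an odds ratio of 1.52 (Fisher's exact test, p = 4.3e-38). The others included all 1093 olfactory receptor genes, of which 8 were marked. They also included all but 1 of the 183 genes on chromosome Y, of which none was marked. Such genes lower the share of the others, and the difference without them was not tested. Around the 5′ ends of marked genes, the median covered share of the 10 kb window was 41.7% for CpG-rich and 28.8% for other promoters. The count of marked promoters depended on the definition. It was 2864 with at least 1000 bp covered and 7671 with a window of 5 kb to each side.

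Genes listed here for more posterior parts of the nervous system were marked without exception in the forebrain. All 39 Hox genes had marked promoters (adjusted exact p = 2.14e-25), as did all 48 transcription factors of midbrain, hindbrain and spinal cord (adjusted exact p = 4.21e-31). The 10 kb windows of Hoxb3, Hoxb4 and Hoxb5 were covered over their whole length. The same held for Prdm12, a regulator of sensory neurons and spinal interneurons, for Pax7, a factor of dorsal midbrain and spinal cord, and for Gata2, which specifies inhibitory neurons of midbrain and spinal cord. The 5′ end of Pax7 lies at position 139833528 of chromosome 4 and that of Gata2 at position 88193891 of chromosome 6 (mm10). Against forebrain-wide transcription factors, of which 48.6% were marked, both lists were higher by 51.4 percentage points. The adjusted exact p was 1.14e-07 for Hox genes, with a lower 95% bound of 8.49 on the odds ratio, and 1.34e-08 for the midbrain, hindbrain and spinal cord factors, with a lower bound of 10.5 (Fisher's exact test, Benjamini-Hochberg over 11 contrasts). Genes within a list are not independent replicates, and neighbouring Hox genes share domains. Listed factors can also act elsewhere: Nkx2-2 is a member of the glial list as well, and Tal1 of the endothelial and mural list. No expression values were used here, so members that also act in parts of the forebrain were not told apart. The contrast therefore compares the lists as named.

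**Figure D1:**
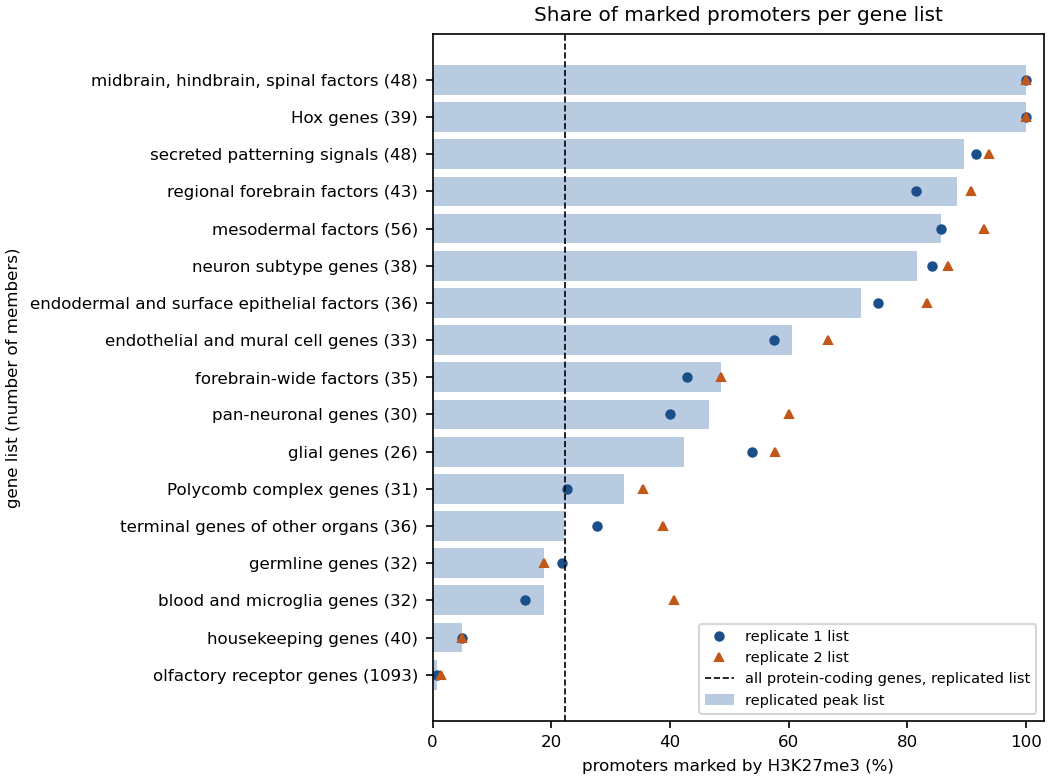
Share of promoters marked by H3K27me3 in each of the 17 gene lists, in percent of list members, with the number of members in parentheses. Bars show the replicated peak list, circles and triangles the lists of replicates 1 and 2, and the dashed line the 22.4% of all protein-coding genes. Hox genes and midbrain, hindbrain and spinal cord factors reach 100% in all 3 lists, while housekeeping genes stay at 5%.

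Transcription factors of the forebrain itself also carried the mark, and those restricted to a region or lineage did so most. Of 43 regional and lineage-restricted forebrain factors, 38 were marked (88.4%, adjusted exact p = 1.37e-19 against all other genes). Lhx6, which specifies cortical interneurons born in the ventral forebrain, was covered over 99.4% of its 10 kb window. Gsx1, a factor of ventral progenitors, was covered over 98.3%, Neurog1, a proneural factor, over 98.2%, and Neurod2, a factor of maturing cortical neurons, over 97.8%. Dmrta2, Lhx5, Fezf2 and Gbx2 lay between 96.1% and 98.1%. The 5 unmarked members were Neurod6, Bcl11b and Foxp1 together with Foxp2 and Tcf7l2, the last pair chosen after their values were seen, and the replicate 2 list marked Foxp2. Of 35 forebrain-wide factors 17 were marked (48.6%, adjusted exact p = 0.00121), with 15 in the replicate 1 list and 17 in the replicate 2 list. Six3, which sets up the anterior forebrain, was the most widely covered with 99.4% of its window (5′ end at position 85613608 of chromosome 17). Nfix followed with 93.6%, Pax6, a factor of dorsal forebrain progenitors and eye, with 92.5% and Pou3f1 with 91.2%. Lhx2, Otx2, Insm1 and Zic1 had between 65.2% and 73.5%. Sox4 and Sox11, which neuronal precursors express broadly, had no covered base in their windows in any of the lists of replicate 1, replicate 2 and replicated peaks. Sox3 on chromosome X was unmarked with 12.6% of its 10 kb window covered. The difference between the regional and the forebrain-wide list was 39.8 percentage points (odds ratio 8.05, 95% interval 2.31 to 31.5, adjusted exact p = 2.54e-04). It compares the lists as named, and the forebrain-wide list is not free of regional factors, Pax6 among them.

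Regulators of mesoderm, endoderm and surface epithelium, lineages outside the nervous system, were marked in most cases. Of 56 mesodermal transcription factors 48 were marked (85.7%, adjusted exact p = 4.22e-23). Pitx1, a hindlimb factor, and Tbx5, a factor of heart and forelimb, were covered over their whole 10 kb windows, and Barx1 over 99.4%. Tbx6 and Msgn1, both of presomitic mesoderm, and Prrx2 were not marked. Of 36 endodermal and surface epithelial factors 26 were marked (72.2%, adjusted exact p = 5.62e-10). Neurog3, which specifies endocrine cells of the pancreas, Cdx2, a factor of the intestine, and Tfap2a, a factor of ectoderm and neural crest, had fully covered windows. Hnf1a, Hnf4a and Hnf4g were not marked, although the replicate 2 list marked Hnf1a. Secreted patterning signals were marked in 43 of 48 cases (89.6%, adjusted exact p = 1.58e-22), with Wnt6, Wnt10a and Wnt10b covered throughout. The unmarked signals were Fgf4, Fgf10 and Fgf20 together with Bmp5 and Nog, the last pair chosen after their values were seen. Each replicate's own list marked Fgf4, and the replicate 2 list marked Nog. Mesodermal factors exceeded forebrain-wide factors by 37.1 percentage points (odds ratio 6.35, 95% interval 2.12 to 19.8, adjusted exact p = 3.48e-04). With a promoter window of 5 kb to each side this contrast no longer passed (adjusted exact p = 0.191). The endodermal and epithelial list exceeded them by 23.7 points and did not pass (odds ratio 2.75, 95% interval 0.927 to 8.34, adjusted exact p = 0.0591), while it passed in the lists of replicate 2 alone (adjusted exact p = 0.00318) and replicate 1 alone (adjusted exact p = 0.00885).

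Genes for particular neuron types were marked far more often than genes shared by all neurons. Of 38 neuron subtype genes 31 were marked (81.6%, adjusted exact p = 3.55e-14). Slc32a1, the vesicular transporter for GABA and glycine, was covered over 99.2% of its 10 kb window, Slc6a5, a glycine transporter, over 98.3%, and Slc18a3, the vesicular transporter for acetylcholine, over 96.0%. Gad1, which makes GABA, Th and Ddc, both of catecholamine synthesis, were not marked, although each replicate's own list marked Th. Of 30 pan-neuronal genes 14 were marked (46.7%, adjusted exact p = 0.00507), with 12 in the replicate 1 list and 18 in the replicate 2 list. They included the intermediate filament genes Nefl, with 65.5% of the window covered, and Ina, with 59.2%, Mapt, which encodes tau, with 55.3%, and Rbfox3, a splicing regulator, with 51.6%. Crmp1 had 62.1%, and Stmn3, Nefm and Stmn2 had between 32.8% and 36.0%. Tubb3, Map2 and Dcx, genes of neuronal microtubules, were not marked, although the replicate 2 list marked Tubb3 and Dcx. The subtype list exceeded the pan-neuronal list by 34.9 percentage points (odds ratio 5.06, 95% interval 1.51 to 17.7, adjusted exact p = 0.00508). This contrast did not pass with a window of 5 kb to each side (adjusted exact p = 0.104), and the pan-neuronal list did not pass with at least 1000 bp covered (20.0% marked, adjusted exact p = 0.356).

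The most widely covered glial genes were Olig1, Olig2 and Nkx2-2, transcription factors of the oligodendrocyte lineage. They were covered over 98.3%, 97.1% and 96.2% of their 10 kb windows. Gfap, Aqp4 and Aldh1l1, genes of astrocytes, were not marked, although each replicate's own list marked Gfap. Marked and unmarked genes occurred in both glial types, and the genes that follow were chosen after their values were seen. Gja1 and Gjb6, gap junction genes, were the only marked members named here for astrocytes. The myelin gene Mbp was marked, and the myelin genes Mog and Plp1 were not. The remaining marked members were Sox10, Sox8, Pdgfra, Cspg4 and Myrf. Unmarked as well were S100b, Slc1a2, Slc1a3, Fabp7, Mag, Mobp, Cnp, Aldoc, Apoe and Sox9. The glial types were not compared by a test. In all, 11 of 26 glial genes were marked (42.3%, adjusted exact p = 0.0392), which no longer passed with 1 gene per 100 kb (adjusted exact p = 0.0662). The glial list did not differ detectably from the pan-neuronal list (difference of −4.36 percentage points, 95% interval of the odds ratio 0.255 to 2.74, adjusted exact p = 0.793).

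Markers of other cell types that a dissected forebrain can contain were marked unevenly. Of 33 endothelial and mural cell genes 20 were marked (60.6%, adjusted exact p = 4.67e-06). Tal1, a factor of blood and endothelium, was covered over 95.4% of its window, Sox7 over 94.7% and Flt1, a receptor for vascular growth factor, over 90.9%. Pecam1, Cdh5 and Tek had no covered base in their 10 kb windows. Of 32 blood and microglia genes 6 were marked (18.8%, adjusted exact p = 0.884), with 5 in the replicate 1 list and 13 in the replicate 2 list. C1qc and C1qa, complement genes of microglia, were covered over 69.7% and 55.6% of their windows and Epor, the erythropoietin receptor, over 54.3%. Ptprc, Cd3e and Cd4 were not marked, although the replicate 2 list marked Cd3e and Cd4.

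Genes that serve other organs or the germline were not all marked. Of 36 terminal genes of liver, muscle, skin and pancreas 8 were marked (22.2%, adjusted exact p = 1). The muscle genes Ckm, Acta1 and Myl7 were covered over 73.7%, 71.8% and 57.6% of their windows. The liver genes Alb and Afp had no covered base, and Apoa2 was not marked, although each replicate's own list marked it. Of 32 germline genes 6 were marked (18.8%, adjusted exact p = 0.884). They included Tdgf1 with 62.0% of its window covered, Pou5f1, a pluripotency factor, with 54.4% and Tdrd1 with 20.7%, whereas Dazl, Ddx4 and Mael were not marked, although the replicate 2 list marked Ddx4. Of 1093 olfactory receptor genes 8 were marked (0.732%, adjusted exact p = 2.38e-107), with Olfr94, Olfr63 and Olfr95 the most widely covered at 37.0%, 16.7% and 14.97%. Against mesodermal transcription factors, the germline and the blood and microglia list were each lower by 67.0 percentage points (difference of −67.0, adjusted exact p = 1.8e-09 for both). The terminal genes had a difference of −63.5 (adjusted exact p = 2.68e-09) and the olfactory receptor genes of −85.0 (adjusted exact p = 8.96e-67). These contrasts set a list of transcription factors against lists not limited to them, so they do not separate lineage from kind of gene.

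Housekeeping genes were nearly free of the mark. Only Gusb and Reep5 of 40 were marked (5%, odds ratio 0.182, adjusted exact p = 0.00933), in both replicates' lists as well, with 3.47% and 17.8% of their 10 kb windows covered. Actb and Gapdh had no covered base in any of the lists of replicate 1, replicate 2 and replicated peaks. Genes of the Polycomb complexes, which write and read H3K27me3, were marked in 10 of 31 cases (32.3%, adjusted exact p = 0.238). Cbx8 was covered over 81.7% of its window, Epop over 75.01%, Cbx4 over 74.4% and Pcgf1 over 54.3%. Phf19, Pcgf5, Cbx2 and Phc2 had between 25.8% and 43.7%, and the replicate 1 list did not mark Cbx2. The core subunits Ezh2 and Eed had no covered base, and Ezh1 was not marked. The list passed with at least 1 bp covered (45.2% marked, adjusted exact p = 0.0120) and with a window of 5 kb to each side (54.8%, adjusted exact p = 0.0290). The cell cycle inhibitors Cdkn2a and Cdkn2b were marked, with 87.3% and 70.9% of their windows covered.

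The 10 H3K27me3 domains with most covered bases included 1 at each of the 4 Hox clusters. Joined across gaps of up to 3 kb, the peaks formed 27181 domains, of which 2529 were longer than 10 kb and held 53.4% of covered bases. The domain with most covered bases spanned Hoxc13 to Hoxc4 on chromosome 15 from 102888929 to 103158187 (269 kb). The HoxA domain on chromosome 6 from 52145933 to 52333566 reached to Evx1 (188 kb). The HoxB domain lay on chromosome 11 from 96226636 to 96385788 (159 kb), and the HoxD domain on chromosome 2 from 74637393 to 74773299 took in Evx2 (136 kb). From the outermost to the outermost Hox gene, peaks covered 95.8% of HoxA, 87.7% of HoxB, 98.0% of HoxC and 96.0% of HoxD. The replicate 1 list covered 95.8%, 84.7%, 97.6% and 94.8% of them, and the replicate 2 list 94.6%, 87.8%, 97.4% and 95.0%. A pair of the 10 leading domains lay on chromosome X. The domain from 99381330 to 99615039 held the 5′ end of Pja1, a ubiquitin ligase gene (234 kb, of which peaks covered 176 kb). The domain from 151981158 to 152231053 held Hsd17b10, Ribc1, Smc1a and Iqsec2 (249.9 kb, of which peaks covered 148 kb). A domain on chromosome 7 from 49603731 to 49776921 held Dbx1, listed here with the midbrain, hindbrain and spinal cord factors, and Htatip2 (173 kb). The remaining 3 held no coding 5′ end, and their overlap with genes was taken over the whole annotated span. The domain on chromosome 11 from 35438349 to 35599498 overlapped Slit3, an axon guidance gene, and the nearest coding 5′ end was that of Pank3. The domain on chromosome 7 from 131705051 to 131828020 overlapped the annotated span of Fgfr2, a growth factor receptor gene. Its nearest coding 5′ end was that of Gpr26. The domain on chromosome 1 from 89644034 to 89774222 overlapped Agap1, and the nearest coding 5′ end was that of Gbx2. The number of domains over 10 kb depended on the joining gap, with 1114 at 1 kb and 4200 at 10 kb. It also depended on the peak list, with higher numbers in the pooled list and in each replicate's own list.

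**Figure D2:**
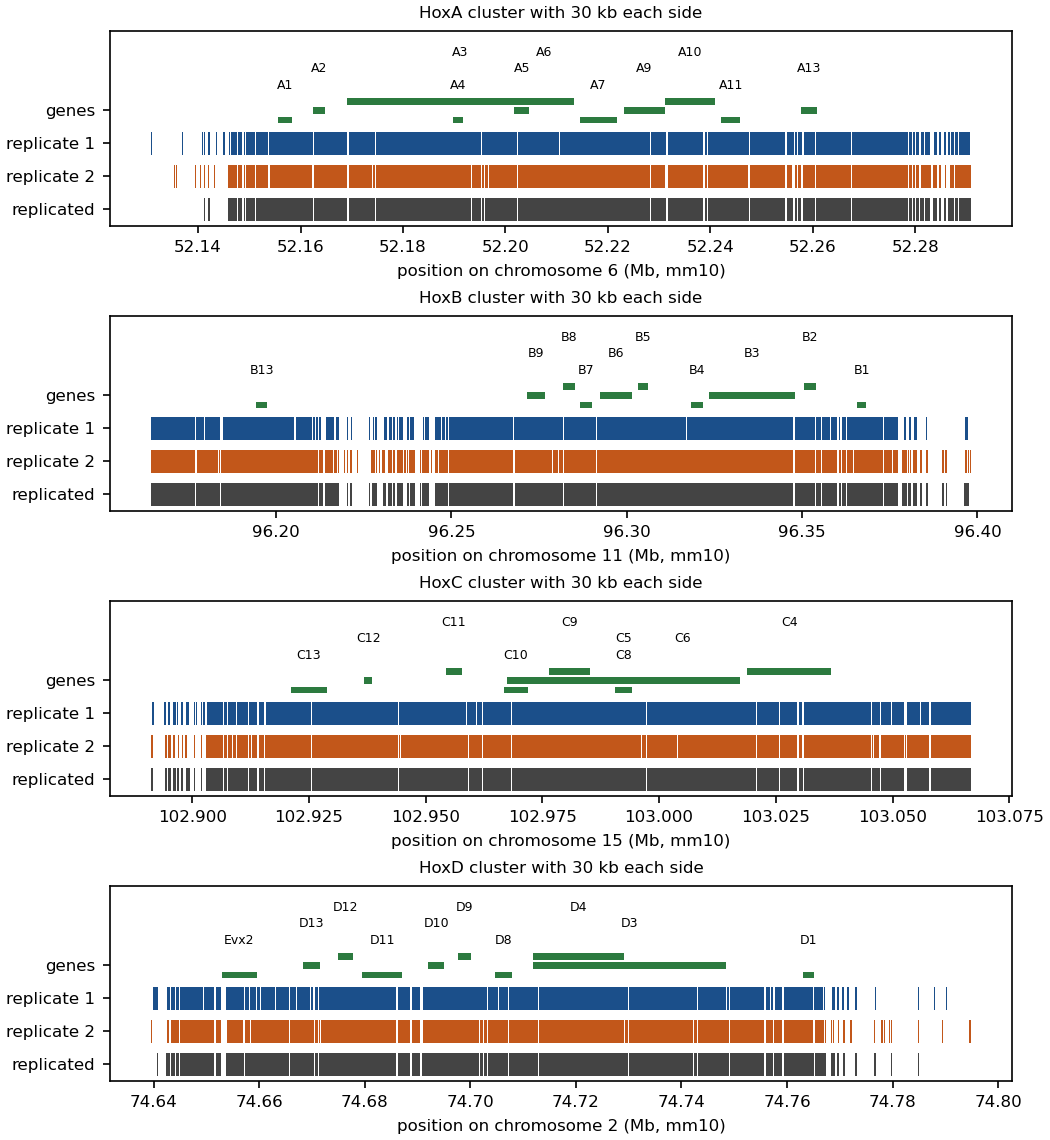
Peaks over the HoxA, HoxB, HoxC and HoxD clusters with flanking sequence, by position in Mb (mm10). In each panel the rows show, from the top, Hox and Evx genes (green), peaks of replicate 1 (blue), of replicate 2 (orange) and replicated peaks (grey). Replicated peaks cover between 87.7% and 98.0% of each cluster, with a gap in HoxB between Hoxb13 and Hoxb9.

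The width of the mark, taken over all members of a list whether marked or not, differed between the gene lists. Hox genes had a median of 97.5% of the 10 kb window covered (interquartile range 95.1% to 99.1%), and midbrain, hindbrain and spinal cord factors 95.4% (82.0% to 98.2%). Mesodermal factors had a median of 90.1%, regional forebrain factors 82.5%, secreted signals 70.8% and endodermal and epithelial factors 70.8%. Neuron subtype genes had 46.2%, forebrain-wide factors 31.9% (1.2% to 57.0%), endothelial and mural genes 20.2%, glial genes 14.95%, pan-neuronal genes 9.87% and Polycomb genes 4.39%. The median was 0 for housekeeping, blood and microglia, terminal, germline and olfactory receptor genes. Unmarked members lower these medians, so they partly restate the share of marked members. Over marked members alone the order changed, with a median of 71.9% for glial genes, 57.2% for forebrain-wide factors and 50.8% for neuron subtype genes. It was 41.0% for marked blood and microglia, 33.9% for marked terminal and 19.6% for marked germline genes. Over all members, the median of forebrain-wide factors was 22.6% in the replicate 1 list and 33.5% in the replicate 2 list. In the same order of lists it was 2.23% and 4.65% for blood and microglia genes and 0.805% and 3.30% for terminal genes.

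**Figure D3:**
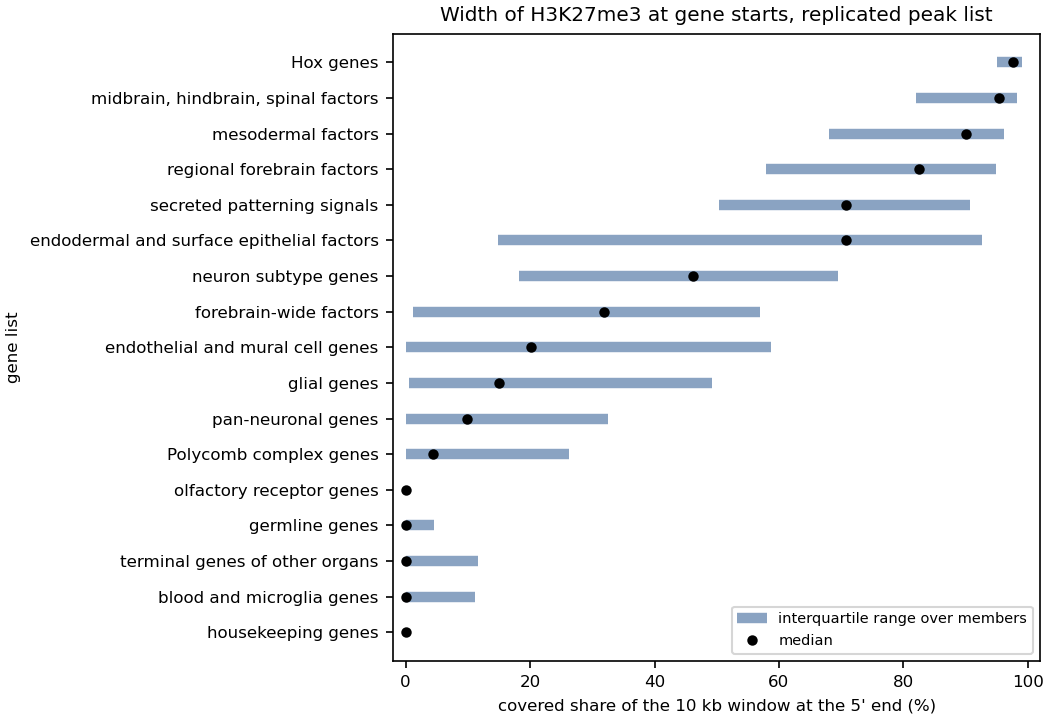
Covered share of the 10 kb window at the 5′ end, in percent, for the members of each gene list in the replicated peak list. Points show the median and bars the interquartile range over members. Hox genes lie near 97.5%, forebrain-wide factors spread around 31.9%, and housekeeping genes lie at 0.

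Chromosome X carried more replicated peaks for its length than any autosome, and they were narrower. In the replicated list it held 52.4 peaks per Mb, against a median of 28.1 over the 19 autosomes (range 17.9 to 52.0), and its median peak width of 411 bp was below that of all 19 autosomes, whose median was 471 bp. Its peaks were not narrower in the replicates' own lists, with 268 bp against 268 bp in replicate 1 and 286 bp against 272 bp in replicate 2. In the lists of replicate 1, replicate 2 and pooled peaks, 2 autosomes each exceeded it in peaks per Mb. Peaks covered 2.89% of chromosome X against an autosomal median of 2.37% (range 1.26% to 4.48%), and 8 autosomes had more. The ratio of X to the median autosome in covered share was 1.16 in the replicate 1 list and 1.15 in the replicate 2 list. No list held a peak on chromosome Y, although the pools held both sexes. How reads from repeated sequence were treated is not given in the sources used here, so this does not show that the mark was absent.

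**Figure D4:**
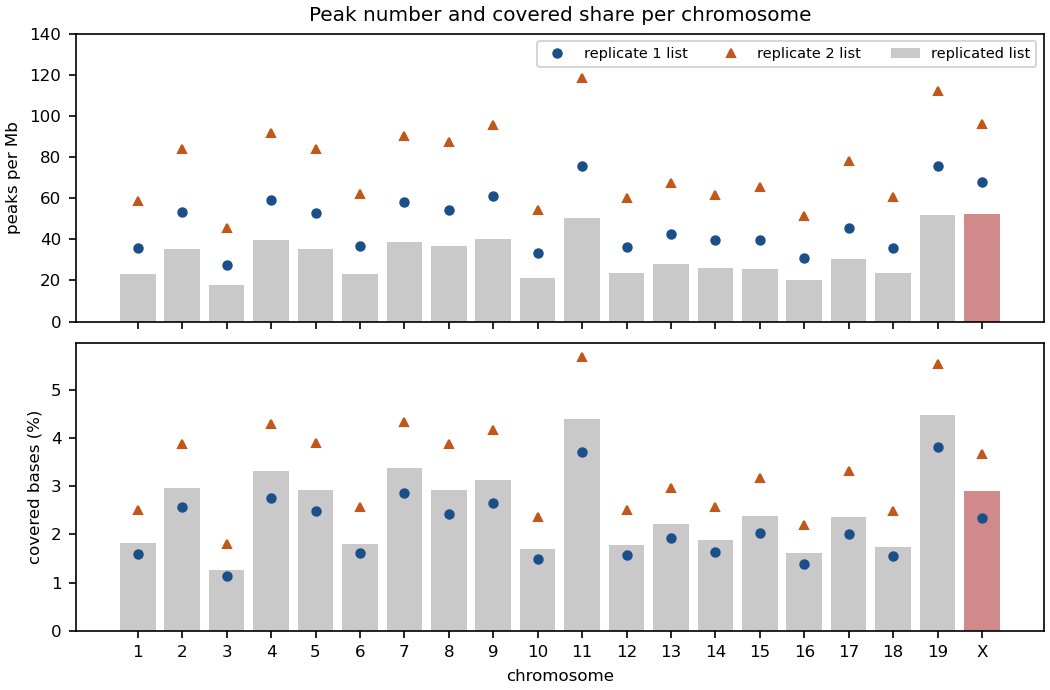
Peaks per Mb (upper panel) and percent of bases covered by peaks (lower panel) for each autosome and chromosome X. Bars show the replicated list, with X in red, and circles and triangles the lists of replicates 1 and 2. Chromosome X has 52.4 replicated peaks per Mb and a covered share of 2.89%.

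Some list members were marked in the peaks of 1 replicate alone. In replicate 2 alone these were led by Prox1, a factor of hippocampal neurons, and Emx2, a factor of cortical progenitors, followed by C1qa, Zic2 and Tnni3. Their covered shares of the 10 kb window in the replicate 2 list lay between 45.0% and 66.0%, against 25.3% to 41.4% in the replicate 1 list. In replicate 1 alone they were led by Cnp, Stag3, Sohlh1, Foxi1 and Olfr464, with shares of 4.56% to 27.8% in the replicate 1 list and 3.98% to 31.7% in the replicate 2 list. The replicated list marked Prox1, Emx2, C1qa, Zic2, Stag3 and Olfr464 and did not mark the others.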

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

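The gene lists, the tests on them and the alternatives were fixed before the data were examined, except 4 settings chosen after seeing the data: replicated peaks that overlap both replicates' peaks, a minimum −log10 q of 5, a background without chromosome Y, and chromosome X in the other lists. Further tests chosen after results were seen are named under the other observations. The higher share of CpG-rich promoters, the overlap of the replicates and the place of peak bases kept their call in each alternative run for them (12, 3 and 4 settings), and so did the Hox genes and the midbrain, hindbrain and spinal cord factors against all other genes. With at least 1000 bp covered, 2864 promoters were marked, pan-neuronal genes fell to 20.0% and no longer passed, Polycomb genes turned to 9.68%, glial against pan-neuronal genes turned to a difference of 14.6 points, and endodermal against forebrain-wide factors passed with 38.0 points. With 5 kb to each side, 7671 promoters were marked and Polycomb genes passed with 54.8%. Mesodermal against forebrain-wide factors (13.2 points) and subtype against pan-neuronal genes (20.2) no longer passed there, and blood genes (43.8%), terminal genes (44.4%) and glial against pan-neuronal genes (6.41) turned direction. With at least 1 bp, Polycomb genes passed with 45.2% and the glial contrast turned to 3.33. With any transcript start, terminal genes turned to 33.3% and the glial contrast to 4.87. With CpG-rich promoters alone, terminal genes turned to 100% (1 gene) and their contrast with mesodermal factors fell to 0, the glial contrast turned to 14.4, and endodermal against forebrain-wide factors passed with 51.7. Blood and olfactory receptor genes gave no value in that setting, having no CpG-rich promoter. With 1 gene per 100 kb, glial genes no longer passed (40%) and terminal genes turned to 25%. In the pooled list, blood genes turned to 31.3%, terminal genes to 36.1% and the glial contrast to 0.513, and endodermal against forebrain-wide factors passed with 29.2. With bases covered in both replicates, terminal genes turned (22.2%), the glial contrast turned to 5.64 and the endodermal contrast passed with 37.9. Terminal genes also turned at a minimum −log10 q of 2 (22.2%) and of 5 (19.4%) and with replicated peaks overlapping both replicates (22.2%), and the endodermal contrast passed at 5 (35.1) and with that overlap (26.5). In the list of a single replicate, blood genes ranged from 15.6% to 40.6%, terminal genes from 27.8% to 38.9%, germline genes from 18.8% to 21.9%, the glial contrast from −2.31 to 13.8 and the endodermal contrast from 32.1 to 34.8. None of these turned lists passed in either direction, and the cause was not tested. The ratio of chromosome X in covered share was 1.23 at a minimum −log10 q of 2, 1.13 at 5, 1.23 in the pooled list and 1.15 to 1.16 in single replicates, and in peaks per Mb it was 1.55 in the pooled list and 1.43 to 1.60 in single replicates. Domains over 10 kb numbered 1114 with a joining gap of 1 kb, 4200 with 10 kb, 4308 in the pooled list and 2718 to 4453 in single replicates. In the pooled list the median covered share of the 10 kb window moved to 75.3% for endodermal factors, 22.7% for glial, 3.77% for blood and 2.98% for terminal genes. In single replicates it ranged from 22.6% to 33.5% for forebrain-wide and 68.0% to 80.7% for regional factors, 96.4% to 97.0% for Hox genes, 91.9% to 92.4% for midbrain, hindbrain and spinal cord, 83.5% to 86.2% for mesodermal and 63.0% to 68.7% for endodermal factors, 62.8% to 70.7% for signals, 8.69% to 14.7% for pan-neuronal, 35.3% to 48.2% for subtype, 2.23% to 4.65% for blood, 12.4% to 19.5% for endothelial, 0.805% to 3.30% for terminal and 0 to 2.01% for germline genes. Of 126 named genes, 112 kept their call without replicate 1 and 113 without replicate 2.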

Other observations

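The tests of gene families, of non-coding genes, of peaks beside the 5′ end, of a mixture of cells and of the detection limit were chosen only after results were seen. Protein-coding gene families were grouped by symbol stem after the data were seen, and 136 stems had at least 15 members outside the 17 gene lists. The counts below take in all protein-coding genes of a stem, list members included. Collagen genes, which build extracellular matrix, were marked in 29 of 45 cases (64.4%, adjusted exact p = 5.87e-08), among them Col13a1, Col8a2, Col4a1 and Col4a2. Synaptotagmin genes, which sense calcium in vesicle release, were marked in 11 of 17 cases (64.7%, adjusted exact p = 0.00362), among them Syt2, Syt6, Syt12 and Syt16. Semaphorin genes, which guide axons, were marked in 11 of 20 cases (adjusted exact p = 0.0128), among them Sema6b, Sema7a, Sema3f and Sema4d. The stem of solute carriers had 124 of 371 marked (33.4%, adjusted exact p = 1.85e-05). Some families had no marked member: 0 of 331 vomeronasal receptor genes (adjusted exact p = 1.88e-35), 0 of 67 histone genes (adjusted exact p = 1.74e-06), 0 of 34 Rhox genes (adjusted exact p = 0.00379) and 0 of 22 Pcdhb genes (adjusted exact p = 0.0297). How reads from near-identical gene copies were treated is not given, so these counts do not show that the mark was absent. Members of a family are not independent replicates. Zinc finger genes with the stem Zfp were marked in 35 of 394 cases (8.88%, adjusted exact p = 7.97e-11).

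Long intergenic non-coding RNA genes were marked less often than coding genes, in 789 of 5854 cases (13.5%, odds ratio 0.541, adjusted exact p = 5.22e-54). Antisense genes were marked in 599 of 2959 cases (20.2%, odds ratio 0.881, adjusted exact p = 0.00942), and 49.9% of these lay within 5 kb of a marked coding 5′ end. Among the marked intergenic ones that share was 19.5%. The share was not taken over unmarked genes of either type, so it does not tell whether a marked neighbour goes with marking. Processed pseudogenes were marked in 361 of 9940 cases (3.63%) and microRNA genes in 223 of 2202 (10.1%). In the replicate lists 13.5% and 21.2% of intergenic non-coding genes were marked.

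Chromosome X held 52.4 replicated peaks per Mb, above all autosomes, an order limited to the replicated list that weak calls did not account for, since the ratio to the median autosome was 1.95 at a minimum −log10 q of 5. Sequence composition was weighed with a fit of peaks per Mb on GC content and gene density over the autosomes, in which X had 9.14 times its predicted value against at most 1.37 for an autosome left out of the fit; X has a lower GC content (39.3%) than any autosome (40.5% or more), so the fit reached beyond its range. The pools held embryos of both sexes per the labels, and H3K27me3 on the inactive X of female cells may add peaks, a hypothesis under which genes that escape inactivation would be covered less. The 5 escape genes Ddx3x, Kdm6a, Kdm5c, Eif2s3x and Pbdc1 had a mean covered share of 6.39% against 6.85% for 254 other X-linked genes with CpG-rich promoters (one-sided permutation p = 0.564). The share was taken over the gene body with 10 kb to each side, so peaks of neighbouring genes count. Kdm5c starts at 152233020, so its window reached into the domain of Smc1a and Iqsec2, which ends at 152231053. The comparison therefore cannot exclude that escape genes themselves are covered less. The 10162 autosomal genes with CpG-rich promoters had a mean of 6.72% and a median of 0.760%, against a mean of 6.85% and a median of 0.680% for the 254 on X, so mean and median differ in direction and the hypothesis stays open until pools of a single sex are compared.

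Members of the forebrain-wide list such as Six3, Pax6 and Lhx2 were marked in forebrain, whose development they direct. The name of the list is not exact, since Pax6 is a factor of dorsal forebrain progenitors. Weak calls do not account for most of it, since 76.5% of the 17 marked members, 13 genes, stayed marked at a minimum −log10 q of 5, against all 48 factors of midbrain, hindbrain and spinal cord. Peaks beside the 5′ end stay open as an explanation, since the central 500 bp was covered to a median of 59.8% with quartiles of 0 and 89.6% (10 of 17 genes reached 50% and 5 had 0), which does not decide for the list. The median of the authors' signal value was 4.50 over the 17 promoters against 9.004 over the 48 others (two-sided permutation p = 1e-05, the smallest the 100000 permutations can give), and such a lower signal is what a mixture of cells with and without the mark could give. This stays a hypothesis that sorted or single cells would have to test, because weaker marking in all cells, or peaks beside the 5′ end, could give the same value.

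Mesodermal factors were mostly marked, and germline, blood and terminal genes mostly not, with no expression values used here to tell which of them were silent. The mesodermal list holds transcription factors alone, whereas the other lists also hold other kinds of gene. Lineage and kind of gene therefore cannot be told apart in this difference. The CpG cut used here does not account for all of this difference. Of CpG-rich promoters 20.0% of 10 germline genes were marked against all 32 of mesodermal factors (Fisher's exact p = 3.81e-07). Of the other promoters 19.4% of 67 blood and terminal genes were marked against 66.7% of 24 mesodermal factors (Fisher's exact p = 5.93e-05). Mesodermal factors were thus themselves marked less often outside CpG-rich promoters. Promoters on the same side of the cut can still differ in CpG content, so a part played by it stays open. A detection limit could account for part of the difference. Blood and terminal genes rose to 39.7% in the longer replicate 2 list, from 20.6% in the replicated list. Mesodermal factors went to 92.9% from 85.7%, and the difference remained in the replicate 2 list (Fisher's exact p = 2.02e-10). How large that part is cannot be told, because a single longer list of unknown depth does not show where the shares would settle. The design has 1 group, so no biological cause could be drawn from a contrast of conditions.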
